A study of Mus musculus with 6 samples.

How the data were processed

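The data are 6 RNA-seq libraries of mouse myeloid cells, 3 from gliomas with wild-type IDH1 (wtIDH1) and 3 from gliomas with mutant IDH1 (mIDH1). Per the labels, the mice were C57BL/6, leukocytes were enriched from dissociated tumours on Percoll, and cells bearing both CD11b and Gr-1 were sorted by flow cytometry. Gr-1 is an epitope shared by Ly6G, found on neutrophils, and Ly6C, found on many monocytes, so this gate can hold both kinds of cell. Per the labels' protocols, polyadenylated RNA was selected and libraries were made with a TruSeq mRNA kit that does not mark strand. Where the exons of a gene and of an antisense gene overlap, their reads can therefore not be told apart.

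The authors deposited 1 table of estimated counts per gene, with 1 column per library and no scaling to library size. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks, Cuffdiff 2.1.1 and HTSeq, and the genome build was mm10. The order and settings of these tools and the annotation release are not given in the sources used here. Between 1.31 and 1.61% of the values in a library were not whole to within 1e-09, and all values were rounded to whole counts before testing. How reads that match several genes were shared is not given in the sources used here, so values of close paralogs, such as members of the Slfn, Oas, Mx, Ly6c and H2-Q families, are uncertain.

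The table held 23107 genes, of which 6810 had 0 counts in all 6 libraries. Ly6g, the cytosolic ribosomal protein genes and the transcripts of the mitochondrial genome were not analysed here, and the result of 1 tested list is not reported here. Library totals ranged from 19728204 to 35093267 counts, so that 3 counts, the number that a count of 0 still allows, corresponded to between 0.0855 and 0.152 CPM (counts-per-million). Floors of this kind cover counting error only. Replicates of a group differed far beyond sampling noise (chi-square per degree of freedom of 50.3 to 149), so each was counted as 1 sample. The labels do not say whether replicates came from separate mice, and p-values measure the spread between these libraries, which may be partly technical.

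Genes were kept with edgeR's filterByExpr at its default minimum count of 10 and minimum total of 15, which left 12950 genes. Libraries were scaled by TMM, and the groups were compared with edgeR 4.0.16 (glmQLFit with default settings and glmQLFTest, group as the only term, 4 residual degrees of freedom) in R 4.3.3. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are mIDH1 minus wtIDH1, with the standard error (SE) from the same test, and levels are CPM scaled by TMM, as mean ± SD. The 37 gene lists were written before the data were examined. Of their 746 genes, 655 were found in the table, 17 of them under an older symbol. The 33 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The same test with an estimated correlation, and fry, were alternatives.

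Genes are named by a rule fixed before the data were examined. It takes 14 genes chosen from the study's question, whatever their result, then the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, leaving out unnamed gene models. For each list described it adds up to 4 members with the smallest p. Coordinates are those of the mm10 build (GRCm38.p6 annotation), counted from 1.

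The tests were tried on simulated counts for mIDH1 against wtIDH1, drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed. Of the 12628 simulated genes that passed the filter, 95 had a true log2 change of 1 in size and 94 of 2, and 22.1% and 60.6% of these were recovered, with 3 false calls (3.70% of calls). In 10 simulations without any change, camera called 1 list in all. Genes were simulated independently, so this does not test the effect of correlated genes. With 200 genes changed the adjustment demands smaller p-values than with more changes, so the recovered shares need not hold for the real comparison. Alternatives covered other scalings, filters, tools (DESeq2 1.42.0 and limma voom), dispersion settings, a replicate block, equal depth and leaving out each library. Corrections for GC content and transcript length and a newer form of the quasi-likelihood fit were added after the data were seen, as were 6 further gene lists.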

Results

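RNA was sequenced from CD11b+ Gr-1+ cells sorted out of mouse gliomas, with 3 libraries from tumours carrying wild-type IDH1 (wtIDH1) and 3 from tumours carrying mutant IDH1 (mIDH1). IDH1 is the cytosolic isocitrate dehydrogenase, and its mutant form in glioma makes 2-hydroxyglutarate. The wtIDH1 libraries held 21538975, 27750515 and 20502713 counts and the mIDH1 libraries 35093267, 31605061 and 19728204. The series title names G-CSF and the suppressive function of myeloid cells, and the comparison asks how the expression of these cells differs between the tumour genotypes. Idh1 itself, on chromosome 1 from 65158616 to 65186479, was at 40.8 ± 7.34 CPM in wtIDH1 and 58.6 ± 17.5 CPM in mIDH1 libraries (SD, n = 3 each; log2 fold change 0.52 ± 0.25 SE, adjusted p = 0.247). A count per gene does not tell wild-type from mutant transcripts, so this value does not check the tumour genotype.

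In cells from mIDH1 tumours 27 of 35 genes induced by type I interferon fell, as did 5 of 20 inflammatory cytokine genes and 6 of 21 immediate early genes, and 9 of 21 macrophage genes rose. None of these lists passed with an estimated correlation (adjusted p = 0.605 for each) or in fry's directional test. Of 12950 genes tested, 1058 passed the threshold, 360 higher and 698 lower in mIDH1, and 603 of them had a log2 fold change of at least 1 in size. Lower genes were 66.0% of these calls, but 54.96% (486 higher, 593 lower) when libraries were scaled by their totals alone. In 1052 of the 1058 genes the groups did not overlap, and the same held for 28.9% of all genes tested, where chance gives 10%. The ribosomal RNA precursor Rn45s took 4.78 ± 1.68% of the counts in wtIDH1 and 6.80 ± 1.11% in mIDH1 libraries. The first principal component of log2 CPM held 33.2% of the variance and separated the groups. Without wtIDH1 replicate 1, 2 or 3 the count was 665, 334 or 364, and without mIDH1 replicate 2 it was 558.

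**Figure D1:**
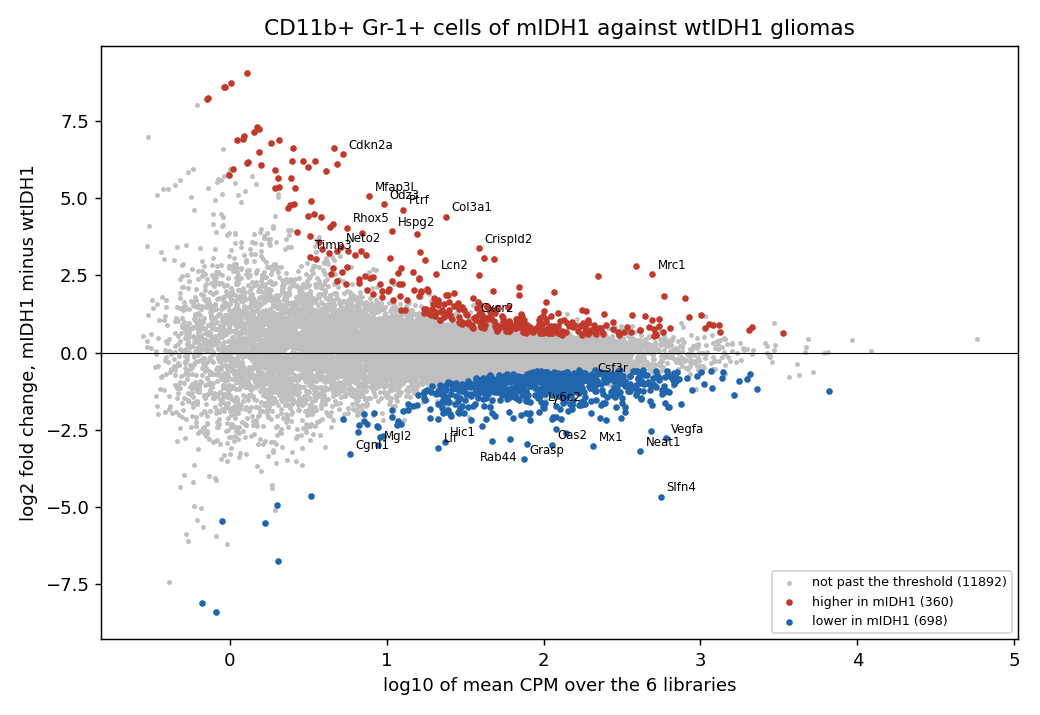
Log2 fold change of mIDH1 against wtIDH1 for each of the 12950 genes tested, plotted against the log10 of its mean CPM over 6 libraries. Red points are the 360 genes higher and blue points the 698 genes lower in mIDH1 at an adjusted p under 0.05, grey points did not pass, and Slfn4 (log2 fold change -4.67) and Cdkn2a (6.43) are among the labelled genes.

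Most genes that type I interferon induces fell in mIDH1. Of 35 tested members, 27 fell and none rose, 34 fell when adjusted over the list alone, all 35 had a negative log2 fold change, and the median was -1.45. Oas2, which senses double-stranded RNA (chromosome 5, 120730333 to 120749886), fell from 202 ± 50.1 to 25.6 ± 2.81 CPM (log2 fold change -2.98 ± 0.22 SE, adjusted p = 3.9e-05). The antiviral GTPase genes Mx1 (chromosome 16, 97447035 to 97462906) and Mx2 had log2 fold changes of -3.03 and -2.86, and Oasl1 one of -2.49. Stat2, which carries the interferon signal to the nucleus, fell from 373 ± 77.4 to 85.2 ± 35.7 CPM (log2 fold change -2.13 ± 0.27 SE, adjusted p = 0.00076). The list passed camera with the preset correlation (adjusted p = 2.2e-17), whereas with an estimated correlation its adjusted p was 0.605. Without wtIDH1 replicate 2 or 3, or mIDH1 replicate 2, 11, 12 or 17 members still fell.

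In other lists tied to interferon a smaller number of members fell. In the list of interferon receptors and STATs, 2 of 14 members fell, Stat2 and the kinase gene Tyk2 (log2 fold change -1.02 ± 0.18 SE, adjusted p = 0.0055), and 6 fell and 1 rose when adjusted over the list alone. In the interferon gamma list 3 of 24 fell, and 3 when adjusted over the list alone: Cxcl10 (-1.65), Gbp6 (-0.88) and Irf8 (-0.76). The groups overlapped for Cxcl10, at 119 CPM in wtIDH1 replicate 1 and 122 CPM in mIDH1 replicate 1. In the MHC class I list 5 of 18 fell, also 5 over the list alone, among them H2-T22 (-2.17), H2-Q4 (-0.96) and Nlrc5 (-1.51), an activator of class I genes. Camera gave adjusted p = 0.012, 0.0044 and 0.0023 for these lists with the preset correlation, against adjusted p = 0.605, 0.703 and 0.605 with an estimated correlation. The interferon gamma list had an adjusted p of 0.261 without mIDH1 replicate 3, and the number of its members that fell was 0 without wtIDH1 replicate 2 or mIDH1 replicate 2, 1 without wtIDH1 replicate 1 or 3, and 12 without mIDH1 replicate 1. Without mIDH1 replicate 1, 7 receptor and STAT genes fell, and without wtIDH1 replicate 2 or mIDH1 replicate 2, 3 MHC class I genes fell. No member of the MHC class II list passed edgeR's test (14 tested, none over the list alone or by DESeq2, 2 at an unadjusted p under 0.05; camera adjusted p = 0.998), but 2 fell without mIDH1 replicate 1 and 1 rose without mIDH1 replicate 3. H2-Aa was at 873 ± 133 CPM in wtIDH1 and 1241 ± 215 CPM in mIDH1 (adjusted p = 0.120).

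Some cytokine genes and early response genes fell as well, while 15 members of each list did not pass. Of 20 inflammatory cytokine genes 5 fell and none rose, and 6 fell when adjusted over the list alone. Il1a fell from 183 ± 29.1 to 55.8 ± 7.32 CPM (log2 fold change -1.71 ± 0.19 SE, adjusted p = 0.00028), Osm from 445 ± 101 to 132 ± 30.9 CPM and Lif from 38.0 ± 5.38 to 4.51 ± 3.54 CPM. Ptgs2, the inducible prostaglandin synthase, had a log2 fold change of -1.36. Of 21 immediate early genes, which tissue dissociation and sorting can also induce, 6 fell and none rose, and 9 fell when adjusted over the list alone, including Atf3 (973 ± 181 to 287 ± 59.8 CPM, log2 fold change -1.76), Egr2 (-1.63) and Fosb (-1.16). Camera gave adjusted p = 0.0023 for the cytokine and 0.00034 for the early gene list, and adjusted p = 0.605 for both with an estimated correlation. Without wtIDH1 replicate 2 the median of the cytokine list moved from -0.68 to -0.30 and 3 early genes fell. Among 21 chemokine genes, 3 fell, Cxcl2 (-1.22), Ccl2 (-0.97) and Cxcl10, whose groups overlapped. Cxcl3 (1.76) and Ppbp rose, and 5 were higher and 6 lower over the list alone. Ppbp was at 0, 0.379 and 0.101 CPM in wtIDH1, around the detection floor, and at 4.71 ± 0.852 CPM in mIDH1, and it passed in 9 of 18 other settings (adjusted p up to 0.128). The list's camera adjusted p was 0.203, or 0.703 with an estimated correlation. With the preset correlation it was 0.029 after correction for GC content and length, where an estimated one was not run, and 7 chemokine genes fell without mIDH1 replicate 3. None rose without wtIDH1 replicate 1 or 2, and 1 rose without wtIDH1 replicate 3, mIDH1 replicate 1 or mIDH1 replicate 2.

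Some macrophage markers rose and some monocyte markers fell, and the difference between these lists was not tested. Of 21 macrophage genes 9 rose and none fell, and 14 rose and 2 fell when adjusted over the list alone. The mannose receptor gene Mrc1 (chromosome 2, 14229414 to 14332023) rose from 146 ± 56.7 to 843 ± 99.6 CPM (log2 fold change 2.53 ± 0.26 SE, adjusted p = 0.00017), and Pf4 (2.07), Ms4a7 (1.46) and Gpnmb (1.16) rose as well. Of 19 monocyte genes 5 fell and 1 rose, or 9 and 1 over the list alone. Ly6c2, which encodes a Ly6C antigen bound by Gr-1 antibodies (chromosome 15, 75108161 to 75112066), fell from 152 ± 54.1 to 45.0 ± 10.4 CPM (log2 fold change -1.76 ± 0.26 SE, adjusted p = 0.0018). Klf4 (-1.63) and Plac8 (-1.94) fell too, while F13a1, a coagulation factor gene of monocytes and macrophages, rose (1.78). Camera gave adjusted p = 0.0023 for macrophage and 0.0099 for monocyte genes, and adjusted p = 0.605 for both with an estimated correlation. Without wtIDH1 replicate 2 or 3, or mIDH1 replicate 3, 2, 3 or 5 macrophage genes rose, and in the last case 2 fell and the list's median moved from 0.85 to 0.45. Of the monocyte genes 2, 3 or 8 fell without wtIDH1 replicate 2, wtIDH1 replicate 3 or mIDH1 replicate 1, and the list had an adjusted p of 0.115 without mIDH1 replicate 3.

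Genes of the neutrophil lists passed in both directions, and which of the sorted cells expressed them was not tested. Of 17 mature neutrophil genes 1 rose and 3 fell, and 4 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.356). Only 1 fell without wtIDH1 replicate 2 or 3, none rose without wtIDH1 replicate 2 or mIDH1 replicate 2, and 2 rose without mIDH1 replicate 1 or 3. Cxcr2, a receptor for neutrophil chemokines, rose from 22.7 ± 3.26 to 50.2 ± 8.09 CPM (log2 fold change 1.15 ± 0.24 SE, adjusted p = 0.013), with adjusted p up to 0.077 when 1 library was left out. Slfn4, listed here but also induced by interferon (chromosome 11, 83175172 to 83190216), had the most negative log2 fold change among the genes named by size, from 1080 ± 428 to 42.4 ± 26.3 CPM (-4.67 ± 0.48 SE, adjusted p = 0.00017). S100a8 was at 4.31 ± 2.53 and 10.3 ± 0.965 CPM (adjusted p = 0.191) and S100a9 at 31.2 ± 10.8 and 48.8 ± 6.40 CPM (adjusted p = 0.175) in wtIDH1 and mIDH1. Of 13 secondary granule genes 3 rose, Lcn2 (2.54), Mmp8 (1.85) and Olfm4 (3.11), and 5 over the list alone (camera adjusted p = 0.048, or 0.605 with an estimated correlation, and 0.540 without mIDH1 replicate 1). Lcn2 lay between 3.33 and 7.71 CPM in wtIDH1 libraries and between 23.1 and 44.5 CPM in mIDH1 libraries. Mmp8 rose from 30.1 ± 7.36 to 109 ± 46.8 CPM and Olfm4 from 0.669 ± 0.243 to 5.82 ± 2.41 CPM. Olfm4 passed in 9 of 18 other settings (adjusted p up to 0.186), 2 genes of the list rose without any 1 of the wtIDH1 libraries, and without mIDH1 replicate 1 there were 2 higher and 1 lower and the list's median moved from 1.19 to 0.54. No primary granule gene passed edgeR's test or DESeq2's (5 tested by edgeR, 1 at an unadjusted p under 0.05, none over the list alone; camera adjusted p = 0.904), but 1 fell without mIDH1 replicate 1. S100a8, S100a9, Lcn2, Mmp8 and Olfm4 were all low beside the lysosomal gene Ctsb, at 2633 CPM in wtIDH1 and 4088 CPM in mIDH1. Other neutrophil list members were higher, such as Slfn4 in wtIDH1 and Csf3r (260 and 148 CPM). The share of neutrophils among the sorted cells was not tested.

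Csf3, the gene of G-CSF, had 0 counts in all 6 libraries, a result that allows up to 0.0855 to 0.152 CPM per library. Its receptor gene Csf3r (chromosome 4, 126023441 to 126044975) fell from 260 ± 12.6 to 148 ± 33.8 CPM (log2 fold change -0.82 ± 0.19 SE, adjusted p = 0.021). Csf3r passed in 13 of 18 other settings, and its adjusted p rose to as much as 0.0946 when a wtIDH1 library was left out. Of 20 genes of G-CSF signalling 4 fell, Csf3r, Tyk2, the kinase gene Pim1 (-1.21) and the survival gene Mcl1 (-0.69), and 6 fell and 1 rose over the list alone (camera adjusted p = 0.0032, or 0.605 with an estimated correlation). Only 1 of them fell without wtIDH1 replicate 2, and 2 without wtIDH1 replicate 3.

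Genes tied to suppression of T cells went both ways. Of 25 members 2 rose and 6 fell, or 3 and 10 when adjusted over the list alone (camera adjusted p = 0.128, or 0.703 with an estimated correlation). With the preset correlation the adjusted p was 0.0277 without mIDH1 replicate 1, where an estimated one was not run. Without wtIDH1 replicate 2 or 3, or mIDH1 replicate 2, 2, 2 or 3 members fell, and 1 rose without mIDH1 replicate 3 or any of the wtIDH1 libraries. Vegfa, a hypoxia-inducible growth factor gene (chromosome 17, 46016993 to 46032377), fell from 1045 ± 161 to 153 ± 71.4 CPM (log2 fold change -2.77 ± 0.31 SE, adjusted p = 0.00033), Tgfb1 fell (-1.01), and Slc7a2, an arginine transporter gene, rose (0.97). Arg1, the arginase gene of suppressive macrophages, was at 1297 ± 349 CPM in wtIDH1 and 570 ± 503 CPM in mIDH1 (log2 fold change -1.19 ± 0.45 SE, adjusted p = 0.136). This value rested on mIDH1 replicate 3, at 1149 CPM against 237 and 324 CPM in the other mIDH1 libraries, and without it the log2 fold change was -2.21 (adjusted p = 4.0e-05, with adjusted p up to 0.384 under other settings). Nos2 (0.11, adjusted p = 0.814) and Cd274, the gene of PD-L1 (-0.60, adjusted p = 0.209), did not pass. Ccr2 (-0.98, adjusted p = 0.165) did not pass either, and mIDH1 replicate 3 was at 61.1 CPM against 247 and 302 CPM in the other mIDH1 libraries. The leukocyte genes Itgam (log2 fold change 0.13) and Ptprc (-0.13) did not pass, with adjusted p = 0.699 and 0.744.

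In lists of metabolism and phagocytosis most members did not pass. Of 31 hypoxia and glycolysis genes 7 fell and 1 rose, or 9 and 1 over the list alone, among them Hk2 (420 ± 43.6 to 211 ± 8.72 CPM, log2 fold change -0.99), Tpi1 (-0.90) and Pfkl (-0.92). None of 43 oxidative phosphorylation genes passed the gene test by edgeR, over all genes or over the list alone, while 10 were at an unadjusted p under 0.05. As higher, 2 passed by DESeq2, with upper-quartile factors or with library totals alone, and 1 with no filter, robust dispersion or the newer quasi-likelihood fit. Of these genes 37 had a positive log2 fold change, with a median of 0.33. Sdhb, for example, was at 51.5 ± 2.62 and 74.4 ± 2.17 CPM (adjusted p = 0.095). Of 26 genes of lysosomes and phagocytosis 5 rose, or 9 over the list alone, including Cd68 (0.67), Mertk (0.90) and Ctsb (0.63). Camera gave adjusted p = 0.016, 0.0012 and 0.022 for these lists, and adjusted p = 0.605, 0.605 and 0.703 with an estimated correlation. No lysosomal gene rose without wtIDH1 replicate 2 or 3, 1 rose without wtIDH1 replicate 1, 1 rose and 2 fell without mIDH1 replicate 3, and 2 rose without mIDH1 replicate 2, and the list's adjusted p reached 0.225 without mIDH1 replicate 3. The hypoxia list's adjusted p was 0.067 without wtIDH1 replicate 2, when 3 members fell, and 0.069 without mIDH1 replicate 2.

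Markers of other cell types of the tumour, several of which the sort should remove, were measured too. Of 18 T and NK cell genes 1 rose, Cd4 (0.65), and none over the list alone, 16 had a positive log2 fold change, and the list had a camera adjusted p of 0.025 (0.703 with an estimated correlation, and up to 0.265 with 1 library left out). None of them rose without wtIDH1 replicate 2, wtIDH1 replicate 3 or mIDH1 replicate 2, 2 rose without wtIDH1 replicate 1, and 5 without mIDH1 replicate 3. Of 16 dendritic cell genes 1 fell, Mgl2 (-2.99), or 2 over the list alone (adjusted p = 0.025, 0.605 with an estimated correlation, and 0.162 without mIDH1 replicate 3), while none fell without wtIDH1 replicate 3 and 3 fell without mIDH1 replicate 1. Of 14 glioma and neural genes 1 rose, as over the list alone, Sox2, a stem cell factor, at 0.0757 ± 0.0756 CPM in wtIDH1 and 4.01 ± 3.38 CPM in mIDH1 (adjusted p = 0.037, up to 0.238 under other settings), and the list did not pass (camera adjusted p = 0.356). DESeq2, run on 24 genes of the list, called 4 higher, and none passed by edgeR without any 1 of the wtIDH1 libraries or without mIDH1 replicate 2. Of 13 microglia genes 1 rose, P2ry13 (1.07), or 2 with 2 lower over the list alone, and of 7 plasmacytoid dendritic cell genes 1 fell, as over the list alone, Bst2 (-1.04), which interferon also induces. Camera gave adjusted p = 0.356 for both lists. No B cell gene passed edgeR's test (7 tested, 1 at an unadjusted p under 0.05, none over the list alone; camera adjusted p = 0.356). No endothelial and pericyte gene did either (7 tested, 2 at an unadjusted p under 0.05, 1 lower over the list alone; camera adjusted p = 0.388), and DESeq2 called 1 gene of each list lower. An endothelial and pericyte gene also fell with limma voom, no filter, the stricter filter, equal depth and the newer quasi-likelihood fit, and without mIDH1 replicate 1. Of 5 platelet genes Pf4 and Ppbp rose, as over the list alone (adjusted p = 0.388), and 1 gene of the list rose with any library left out. Without wtIDH1 replicate 2 or 3 no microglia or plasmacytoid dendritic cell gene passed.

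The lists that follow did not pass camera. No cell cycle gene passed edgeR's test (36 tested, adjusted p = 0.639), nor any lipid handling gene (19 tested, adjusted p = 0.365), and none did over the lists alone. At an unadjusted p under 0.05 there were 1 and 8, and DESeq2 called 1 cell cycle gene lower and no lipid gene. By edgeR 1 cell cycle gene fell with no filter or without mIDH1 replicate 3, and 2 lipid genes rose with no filter or without mIDH1 replicate 1, and 1 without mIDH1 replicate 3. Of 23 unfolded protein response genes Dnajb9 (0.83) and Canx (0.57) rose (adjusted p = 0.813 for the list), and of 8 NADPH oxidase genes Ncf4 fell (-0.68; adjusted p = 0.904). Counts over the list alone were 2 higher for the former, and 2 higher with 1 lower for the latter. Of 20 chemotactic receptor genes Cxcr2 and Fpr1 (1.23) rose and Ccrl2 fell (-1.09; 3 higher and 2 lower over the list alone, adjusted p = 0.772). Of 19 adhesion genes Amica1 (1.36) and Vcam1 (1.96) rose and Itga5 fell (-0.85; 2 higher and 1 lower over the list alone, adjusted p = 0.997). Without wtIDH1 replicate 2 or 3 no unfolded protein response, NADPH oxidase or adhesion gene passed, and no chemotactic receptor gene rose without wtIDH1 replicate 2 or mIDH1 replicate 2. For the platelet, NADPH oxidase and adhesion lists the median, the mean and the test differed in sign. Lists of basophil, eosinophil and mast cell genes and of erythroid genes had 2 tested members each and were not tested.

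Altogether 15 of the 33 lists passed with the preset correlation, 5 higher and 10 lower. None passed with an estimated correlation (smallest adjusted p = 0.605) or in fry's directional test (smallest adjusted p = 0.081), while 25 passed fry's test for change in either direction. Regrouping the 6 libraries as wtIDH1 replicate 1 with mIDH1 replicates 2 and 3 against the others also gave 15 lists with the preset correlation.

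**Figure D2:**
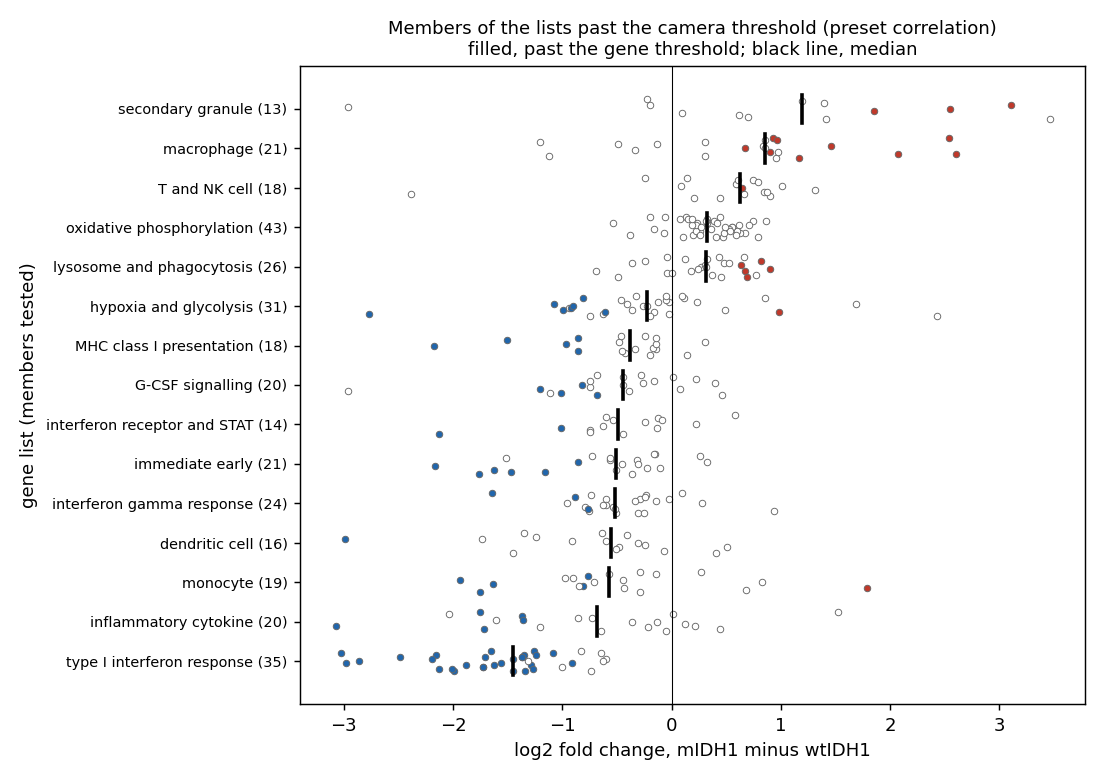
Log2 fold change of mIDH1 against wtIDH1 for each tested member of the 15 lists that passed camera with the preset correlation. Filled points passed the gene test (red higher, blue lower), open points did not, and black lines are list medians, which run from -1.45 for type I interferon genes to 1.19 for secondary granule genes (0.54 without mIDH1 replicate 1).

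The 10 largest increases among genes with a mean of at least 5 CPM and groups that did not overlap were all in genes at 6.84 CPM or less in wtIDH1. Cdkn2a, a cell cycle inhibitor locus (chromosome 4, 89274473 to 89294619), was at 0.115 ± 0.0321 CPM in wtIDH1, near the detection floor, and at 10.5 ± 2.06 CPM in mIDH1 (log2 fold change 6.43 ± 0.76 SE, adjusted p = 0.00042). Col3a1, a fibrillar collagen gene (chromosome 1, 45311538 to 45349706), rose from 2.16 ± 1.11 to 45.9 ± 12.8 CPM (4.41 ± 0.43 SE, adjusted p = 0.00015). The basement membrane gene Hspg2 (3.93), the caveolar gene Ptrf (4.63), Timp3 (3.88), Crispld2 (3.38), Mfap3l (5.07) and Odz3 (4.82) rose as well. Timp3 shares exonic bases with Syn3 on the opposite strand, and reads of the shared bases cannot be told apart without strand. Of the genes named above, Oasl1, Tyk2, Nlrc5, H2-T22, H2-Q4, Il1a, Cxcl10, Pim1 and Cd274 likewise overlap a gene on the opposite strand. So do F13a1, Slc7a2, Tpi1, Ctsb, Amica1 and Vcam1, while Gbp6, Olfm4 and Itgam overlap a gene on the same strand. Rhox5 (4.04) and Neto2 (3.41) rose with adjusted p = 0.030 and 0.044, and reached adjusted p = 0.119 and 0.170 under other settings.

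Among the largest decreases, Neat1, a nuclear long noncoding RNA that builds paraspeckles (chromosome 19, 5824708 to 5845480), fell from 747 ± 219 to 82.3 ± 14.8 CPM (log2 fold change -3.18 ± 0.24 SE, adjusted p = 3.9e-05). Grasp, a scaffold protein gene, fell from 137 ± 32.6 to 12.5 ± 3.71 CPM (-3.45 ± 0.28 SE, adjusted p = 4.3e-05), and Rab44 fell from 138 ± 33.3 to 17.6 ± 6.07 CPM. Hic1 (-2.89) and Cgnl1 (-3.28) fell with adjusted p = 0.0088 and 0.034, and reached adjusted p = 0.056 and 0.176 without wtIDH1 replicate 2, as Mgl2 reached 0.074 without wtIDH1 replicate 3. Of the other genes named above that passed, Amica1, Bst2, Canx, Cd4, Cd68, Ctsb, Cxcl10, Cxcl3, Dnajb9, Fpr1, Gbp6, Gpnmb, Irf8, Itga5, Mcl1, Mertk, Ms4a7, Ncf4, P2ry13, Pfkl, Pim1, Plac8, Tgfb1 and Vcam1 did not pass in at least 1 setting, with highest adjusted p values from 0.0505 (Pim1) to 0.206 (Gbp6).

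**Figure D3:**
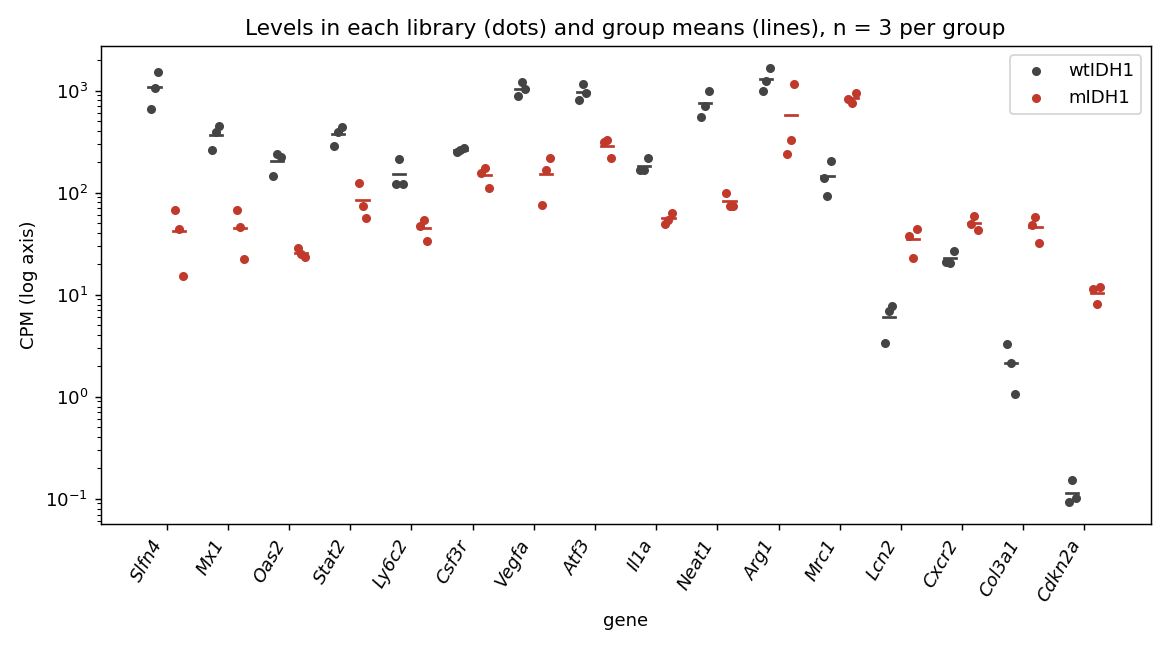
CPM of 16 named genes in each library on a log axis, with dots for libraries (3 per group) and lines for group means. Slfn4 lay at 42.4 CPM on average in mIDH1 against 1080 CPM in wtIDH1, and the mIDH1 library with high Arg1 (1149 CPM) is replicate 3.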

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

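Most alternatives were chosen before the data were examined. The GC content and length correction and the newer quasi-likelihood fit were chosen after the data were seen. The installed edgeR uses the older quasi-likelihood fit by default, so the older fit listed as an alternative is the fit reported and was not run separately. The 1058 genes past the threshold became 1698 with DESeq2, 603 with a log2 fold change of at least 1 required as well, and between 334 and 1033 with 1 library left out. The other settings without a replicate block gave between 848 (GC content and length offsets) and 1311 (no filter). Of the genes shared between each setting and the reported fit, 0 changed sign. With library totals alone, 486 were higher and 593 lower, so that the lower share moved from 66.0 to 54.96%. The replicate block gave 585 genes, 574 of them shared with the reported calls, and 15 lists. Libraries of the same number correlated at -0.03, 0.03 and -0.05 in their deviations from the group means, and those of different numbers between -0.04 and 0.07. These values show no sign of pairing. With 3 libraries per group they cannot exclude it, and the labels do not say what the numbers mean. The 15 lists became 0 with an estimated correlation, 0 in fry's directional test and 25 in fry's mixed test, and between 11 and 14 with 1 library left out. In 8 of the 15 lists the call held with each library left out. The cause of these differences was not tested, except that leaving out a library removes a degree of freedom and the fold threshold removes genes by construction. Of 2675 pairs of a named gene and a setting, 2415 stayed on the same side of the threshold, 177 lost and 83 gained a call, and 0 changed direction while called. Of the 81 named genes past the threshold, 42 passed under all 18 settings. Simulated changes of 2-fold were recovered in 22.1% of 95 genes, so a gene that did not pass may still differ by that much.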

Other observations

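The gene lists of this part were written after the data were seen, and the tests here were chosen after the results were seen, except the test of interferon genes under other scalings and the regrouping count for lists. The GC content and length tests were chosen after a trend of fold changes on GC content had been seen. Of 45 genes in a list written for nuclear speckles and splicing, 27 fell and none rose in mIDH1. Examples are the cyclin gene Ccnl2 (193 ± 15.3 to 45.4 ± 1.26 CPM, log2 fold change -2.09), the splicing factor gene Prpf38b (-1.83) and the splicing kinase gene Clk3 (-1.33). Ankrd11 (-1.92), a chromatin regulator gene, was in the list too. The list holds genes whose decrease prompted it and was not tested without them, so its count is no independent evidence of a fall of such genes. Of 20 genes of NF-kB subunits and regulators, with its targets Cd83 and Icam1 among them, 12 fell and none rose, including Nfkbie (-1.76), Nfkbid (-1.94) and Cd83 (-1.55), and the same limit holds for this list. Neat1 and Malat1 fell, the latter from 9345 ± 2110 to 3940 ± 491 CPM (-1.25), and the other 11 of 13 nuclear long noncoding RNAs did not pass.

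Of 5 Y-linked genes, Ddx3y had 0, 1 and 0 counts in wtIDH1 replicates 1 to 3 and 18, 61 and 89 in mIDH1, and Uty had 3, 0 and 1 against 10, 45 and 21. Eif2s3y had 0, 0 and 1 against 42, 12 and 0, Kdm5d had 0 in wtIDH1 against 0, 6 and 0, and Usp9y had 0 in all 6 libraries. The sexes of the mice and of the tumour cells are not given in the sources used here, so the cells these counts come from are unknown. Xist was between 646 and 978 CPM in all 6 libraries.

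Of the 10 splits of the 6 libraries into 3 and 3, only the real one gave genes past the threshold by edgeR, 1058, and the highest of the other splits gave 0, with between 201 and 700 genes at an unadjusted p under 0.05. Each of the other splits puts libraries of both groups on the same side, so a group difference adds to the spread within sides. A count near 0 was thus likely beforehand, and the contrast with 1058 is no support for the grouping. For lists with the preset correlation, 2 of the 10 splits gave as many as the real split's 15, the real one included. Each of the other splits called lists, between 3 and 15, although none had a gene past the threshold. With 10 splits no share under 0.05 can be reached.

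Among genes past the threshold, more fell than rose in mIDH1, while the median log2 fold change of all tested genes was 0.055. The lower share stayed at 66.0% when trends on GC content and length were taken out of each library, which argues against those trends as the whole cause. This correction moved the median log2 fold changes of the genes lowest and highest in GC content (20% each) from 0.21 and -0.14 to 0.07 and 0.04. The direction of the reported calls varied with GC content. In the lowest 20%, 101 rose and 73 fell, and in the highest 51 rose and 254 fell. After correction, 48 rose and 100 fell in the lowest, and 66 rose and 139 fell in the highest. Of the 1058 reported calls, 763 were shared with the corrected fit. A lower recovery of nuclear RNA is argued against by Xist, whose log2 fold change lay 1.51 ± 0.26 (SE) above that of Malat1 and which did not fall. The scaling may account for part of the skew, since the lower share was 54.96% with library totals alone, just under the 55% set for this test, 56.9% with upper-quartile factors and 66.5% with RLE factors. An effect of tumour genotype on these cells stays open and was not tested apart from these.

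Type I interferon genes were lower in mIDH1. Scaling and depth are argued against, since at least 27 of 35 members fell under RLE, upper-quartile and library-total scaling and at equal depth, and GC content and length are argued against by the 29 that fell after their correction. A smaller share of Ly6C-bearing monocytes may contribute. The median of 18 monocyte markers lay 0.95 above that of the interferon list, a gap that counts against it. The gap was just over the bound used for this test, the markers' SD of 0.93. That SD is the spread of single markers and not the error of their median. Several of those markers are also expressed in macrophages, so a bound on Ly6c2 was added after that narrow result was seen, and Ly6c2 itself lay below the interferon median (difference -0.30, where the SE of Ly6c2's own log2 fold change was 0.26). A smaller monocyte share and an effect of tumour genotype therefore cannot be told apart here, and the latter was not tested.

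Of 27 tested genes of the matrix list, which holds the genes that prompted it, 9 rose and none fell in mIDH1, and 7 of the 27 were at 5 CPM or more in wtIDH1. Carry-over of tumour or stromal cells, which the CD11b and Gr-1 sort should remove, is a candidate source, and the counts of Ddx3y and Uty, higher in the same libraries, do not decide it while the sexes are unknown. The 19 members not seen before the list was written had a median log2 fold change of 1.11, with 3 higher and none lower and p = 0.057 by camera with an estimated correlation, which leaves it open. The most abundant of the list in mIDH1 were Lamc1 (94.2 ± 2.70 CPM), Igfbp4 (67.5 ± 10.4 CPM) and Col3a1 (45.9 ± 12.8 CPM), and of the glioma and neural list Mbp, at 82.1 CPM in wtIDH1 and 75.3 CPM in mIDH1. Carry-over of blood vessel cells also stays open, as the summed endothelial genes differed by -0.0470 on the log2 scale with an SE of 1.20, and expression by the myeloid cells themselves was not tested.

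Fkbp5 rose from 68.2 ± 5.81 to 378 ± 71.6 CPM (log2 fold change 2.47) and Tsc22d3 by 1.06, and both are induced by glucocorticoids. Of 33 genes of the glucocorticoid list 12 rose and 2 fell. The hypothesis of a different glucocorticoid exposure was tested on the 22 listed genes other than the 11 that prompted the list. Their median log2 fold change was 0.43, 2 rose and 2 fell (Per1 and Cdkn1a), and camera with an estimated correlation gave p = 0.586, so these genes do not decide it.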
